A study of Mus musculus with 20 samples.

How the data were processed

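RNA from colon polyps and colon mucosa of mice was sequenced as 20 libraries in 6 groups. Polyps came from shAPC and shAPC/Kras mice on doxycycline (dox) and after its withdrawal, with 4 libraries in each of these 4 groups. Mucosa came from shRenilla mice on and off dox, with 2 libraries in each group. Per the labels' protocols, 4-hydroxytamoxifen at 0.5 mg/ml was injected under the skin at 6 weeks of age and the mice were then fed dox chow. Tumours were taken 4 to 6 weeks later, and off-dox tumours were taken 4 days after the dox chow was removed. RNA was extracted with Trizol, libraries were made with the TruSeq RNA v2 kit and were sequenced on an Illumina HiSeq instrument, per the labels' protocols. That kit does not mark strand.

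The deposited files used here hold whole-number counts of reads per gene, which the authors made with HTSeq 0.5.4 after alignment with STAR 2.3.0e, per the submitters' processing notes. The notes also name DESeq 1.18.0 and the builds mm9 and hg19; all libraries are labelled mouse. The strand setting of the counting and the annotation release are not given in the sources used here, so antisense and overlapping genes cannot be told apart. Reads from near-identical copies, such as the Defa genes, may have been split or lost in counting, and values of these genes are uncertain to that extent. Each file gave gene symbols beside Ensembl identifiers and no coordinates, so no positions are printed. A table of scaled counts for the whole series was not used.

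Counts in genes summed to 19.2 to 35.2 M per library, with a median of 27.2 M, and 19021 to 20842 genes had at least 1 count. Entries that name no gene (reads without a feature, ambiguous, unaligned or aligned to several places) held 32.4% to 40.1% of each file's total, with a median of 37.8%, and were kept out of library sizes and tests. Mitochondrial genes took 1.84% to 4.17% of gene counts and the 10 most abundant genes took 4.24% to 14.9%. Of 37620 genes, 17401 passed edgeR's filterByExpr (minimum count 10, minimum total 15) and were tested. TMM scaling factors ranged from 0.751 to 1.19. Among 26 pairs of replicate libraries, Spearman correlation across genes was 0.964 to 0.995, and the lowest chi-square per degree of freedom was 12.4. Spread between replicates was therefore far above counting error.

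All 20 libraries entered a single edgeR quasi-likelihood fit of group means (glmQLFit with robust estimation, glmQLFTest; edgeR 4.0.16, limma 3.58.1, R 4.3.3), so the groups of 2 libraries shared the estimate of spread with the others. P-values were two-sided and adjusted by Benjamini-Hochberg over the 17401 genes in each of 10 comparisons, and a gene was called when its adjusted p was under 0.05. Levels are CPM, the counts of a gene per M of the TMM-scaled library total, given as mean ± SD over libraries, and log2 fold changes are given ± SE. The labels do not state that libraries come from separate animals, so p-values measure the spread between these samples. In shAPC/Kras polyps off dox, libraries 3 and 4 differed by a chi-square per degree of freedom of 13.1. Either of them with 1 or 2 gave 134 to 175. Libraries 2 and 3 of shAPC/Kras on dox (12.4) and 1 and 2 of shAPC off dox (16.7) were also close. Whether such pairs share an animal is not known, and the fit counted them as separate replicates.

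The 25 gene lists, the named genes, the tests and most alternatives were fixed before the data were examined. The lists were Wnt target, intestinal stem cell, proliferation, ribosome biogenesis and Myc target, absorptive colonocyte, goblet cell, Paneth cell and antimicrobial, enteroendocrine, tuft cell, pan-epithelial, MAPK pathway output, fetal-like and YAP target, interferon response, immediate early and stress, fibroblast, smooth muscle, endothelial, enteric neuron and glia, T cell, B and plasma cell, macrophage, neutrophil, squamous epithelium, posterior Hox and small intestinal genes. Together with the sex-linked genes used to check animal sex, they held 350 genes, of which 343 were tested. Some genes are in several lists, so counts of different lists are not separate results. Lgr5, Ascl2, Axin2, Rnf43, Cd44 and Sox9 are in both the Wnt target and the intestinal stem cell list. Myc and Ccnd1 are in both the Wnt target and the MAPK pathway output list. The genes to be named in a comparison were the 8 largest rises and 8 largest falls (fewer in the later comparisons) among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups compared. Unnamed gene models, immunoglobulin or T cell receptor segments and sex-linked genes were left out of that part. To these were added up to 4 members of each list with the smallest p, and always Apc, Kras, Axin2, Lgr5, Myc, Mki67, Krt20 and Muc2. Counts of list members use calls over all genes tested; the count adjusted over the list alone is given where it differed.

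Lists were tested with camera on log2 CPM with a preset correlation between genes of 0.01, adjusted over the 25 lists, and again with an estimated correlation. Camera called 129 of 250 list tests with the preset value and 12 with the estimated one. The calls that held were those of Wnt target, fetal-like and YAP target, enteric neuron and glia and squamous epithelium genes in both on-dox polyp groups against mucosa, and of fetal-like and YAP target and squamous epithelium genes in both off-dox polyp groups against mucosa. Fry was run as well; its directional p tests whether the genes of a list move on balance in a single direction and its mixed p whether they change in either direction, and neither compares the list with other genes. In 22 of the 250 tests the median, the mean and the camera direction of a list differed in sign, and camera called none of these.

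A gene with no counts in a group is given a bound, the other group's level over a floor of 3 counts in that group; with 1 to 3 counts the ratio is given with its 95% counting interval. These intervals and floors cover counting error only. The fit was tested on simulated counts with seeded changes. At a true change of 2-fold it recovered 59.7% of changed genes for shAPC polyps off against on dox, 70.4% for shAPC/Kras polyps off against on dox, 39.7% for shAPC polyps against mucosa on dox, and 31.9% for the difference of the withdrawal responses. For mucosa off against on dox it recovered 41.3%, with 16937 to 16978 genes tested over the 10 comparisons. Few genes were changed in these simulations, such as 67 at 2-fold for shAPC polyps off against on dox. In that comparison of the real data 4869 genes were called. The adjusted threshold is less strict where many genes change, so these shares do not measure the power of such tests. The camera step called the 1 list that had been shifted and 1 of the 24 others. The shifted list was that of Wnt target genes, which shares members with other lists.

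Alternatives were DESeq2 size factors, no filter, the DESeq2 Wald test (1.42.0), limma-voom with sample weights, only the groups compared, the replicate number as a block, leaving out each library, and the 4 mucosa libraries pooled. Sex of the animals as a covariate, read from Xist and genes of the Y chromosome, and shAPC/Kras polyps off dox without libraries 3 and 4 were added after the data were seen.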

Results

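Gene expression was measured by RNA sequencing in mouse colon polyps and mucosa carrying hairpin RNAs that dox switches on. The shAPC hairpin targets Apc, a scaffold of the complex that degrades beta-catenin and restrains Wnt signalling, and the shRenilla hairpin has no target in the mouse. shAPC/Kras polyps carry the Apc hairpin with an altered Kras gene, a switch protein upstream of the MAPK cascade; the labels do not name the allele. The 6 groups were shAPC polyps on dox (n = 4) and off dox (n = 4), shAPC/Kras polyps on dox (n = 4) and off dox (n = 4), and shRenilla mucosa on dox (n = 2) and off dox (n = 2). Off-dox polyps had been without dox for 4 days. The depth of the libraries ranged from 19.2 to 35.2 M counts in genes. The first 4 principal components of log2 CPM took 43.9%, 17.5%, 12.3% and 5.64% of the variance.

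Apc itself followed the labels in all 20 libraries. Apc (ENSMUSG00000005871) stood at 41.7, 40.8, 56.4 and 63.7 CPM in the shAPC polyps on dox and at 61.7, 42.6, 43.7 and 45.4 CPM in the shAPC/Kras polyps on dox. After withdrawal it stood at 69.7, 71.4, 92.1 and 99.4 CPM in shAPC polyps and at 86.4, 84.3, 90.6 and 87.3 CPM in shAPC/Kras polyps. The mucosa libraries had 136 and 167 CPM on dox and 158 and 163 CPM off dox. Apc rose after withdrawal by a log2 fold change of 0.71 ± 0.16 (SE, adjusted p = 0.003) in shAPC polyps and of 0.85 ± 0.16 (adjusted p = 0.00034) in shAPC/Kras polyps. It remained below off-dox mucosa in both, at log2 fold changes of -0.95 ± 0.18 and -0.89 ± 0.18.

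**Figure D1:**
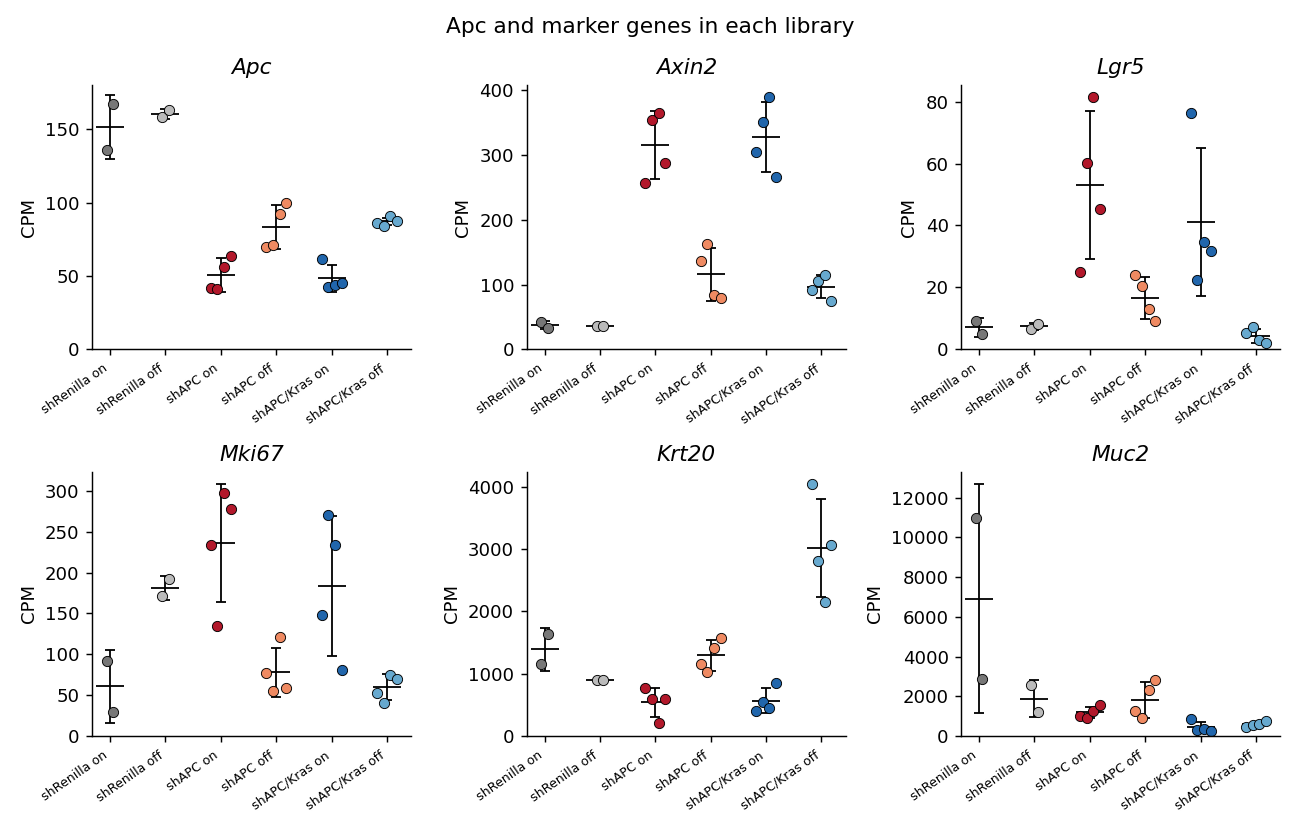
Levels in CPM (vertical axes, from 0) of Apc, Axin2, Lgr5, Mki67, Krt20 and Muc2 in each library, by group; points are libraries, horizontal bars the group mean and whiskers 1 SD (n = 4 for polyps, n = 2 for mucosa). All 8 on-dox polyp libraries lay at or below 63.7 CPM of Apc, and all 4 mucosa libraries lay at 136 CPM or above.

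To ask what distinguishes polyps with silenced Apc from mucosa with the neutral hairpin, shAPC polyps on dox were compared with shRenilla mucosa on dox. Wnt target genes were higher in polyps without exception, 23 of 23 measured. Notum, a secreted Wnt deacylase, was at 201 ± 44.4 CPM (SD, n = 4) against 0.38 ± 0.0653 (n = 2), a log2 fold change of 9.03 ± 0.53 (adjusted p = 2.9e-08). Wif1, a secreted Wnt inhibitor, differed by 7.70 ± 0.48, and Axin2, a feedback inhibitor of Wnt signalling, by 3.08 ± 0.30, from 37.4 ± 6.01 to 315 ± 52.1 CPM. Of 18 intestinal stem cell genes, 13 were higher (14 adjusted over the list alone) and 1 was lower; Lgr5, the R-spondin receptor of crypt base stem cells, differed by 2.90 ± 0.64. Proliferation genes were higher in 17 of 20 (18 adjusted over the list alone), among them the DNA synthesis enzyme subunit Rrm2 at 2.20 ± 0.45 and the mitotic kinase Aurka at 2.03 ± 0.45. Of 20 ribosome biogenesis and Myc target genes, 6 were higher and 1 was lower, with the cell cycle kinase Cdk4 at 1.20 ± 0.13.

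Genes of differentiated epithelium were lower in the same shAPC polyps. Absorptive colonocyte genes were lower in 21 of 26, and the water channel Aqp8 fell from 916 ± 510 CPM in mucosa to 7.47 ± 3.79 CPM, a log2 fold change of -6.94 ± 1.04. Goblet cell genes were lower in 14 of 16, including the mucus protein Fcgbp (-3.77 ± 0.62), the transcription factor Atoh1 (-2.61 ± 0.44) and Klf4, a factor of terminal differentiation (-2.31 ± 0.28). The size of this gap depends on the mucosa group. The mean log2 CPM of the goblet list was 6.63 ± 0.43 in these polyps, 9.04 ± 0.48 in on-dox mucosa and 7.75 ± 0.71 in off-dox mucosa. Fcgbp was at 1080 ± 229, 14800 ± 7880 and 3540 ± 2110 CPM in the same groups. Muc2, the main gel-forming mucin, was at -2.54 ± 0.54, but its call was lost without shRenilla on dox 1 (adjusted p = 0.12). The calls of Mki67, a marker of cycling cells (1.95 ± 0.53), and of Krt20, a keratin of mature colonocytes (-1.36 ± 0.37), were lost without shRenilla on dox 2 (adjusted p = 0.1 each). The tuft cell kinase gene Dclk1 was at -3.01 ± 0.45, and 8 of 11 tuft cell genes were lower. Pan-epithelial genes moved little, with 1 of 10 higher, 2 lower and 7 not called.

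Other groups that differed in shAPC polyps included fetal-like and YAP target genes, with 9 of 14 higher (11 adjusted over the list alone). Tacstd2, a surface glycoprotein of fetal epithelium, was at 93.1 ± 24.1 CPM against 0.191 ± 0.152 (log2 fold change 8.90 ± 0.68), and the secreted phosphoprotein Spp1 differed by 5.49 ± 0.74. MAPK pathway output genes were higher in 9 of 21 and lower in 2; the MAPK phosphatase Dusp4 was at 2.36 ± 0.22. Neutrophil genes were higher in 9 of 12, with the gelatinase Mmp9 at 3.81 ± 0.42, and macrophage genes in 5 of 12. Smooth muscle genes were lower in 10 of 10 and enteric neuron and glia genes in 9 of 10. The muscle intermediate filament Des fell from 907 ± 608 to 11.5 ± 6.88 CPM and the neuronal hydrolase gene Uchl1 was at -3.56 ± 0.37, while 2 of 12 fibroblast and 5 of 10 endothelial genes were lower. Some genes were nearly confined to 1 tissue. Irx5, a homeobox factor, had 0 counts over the mucosa group and was at least 221-fold higher in polyps; the cytokine gene Cxcl3 was at least 184-fold higher. Cfd, the adipocyte protease adipsin, had 3 counts over the polyp group, 958-fold below mucosa (counting interval 327 to 4650).

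By edgeR, 7594 of 17401 genes were called between shAPC polyps and mucosa on dox, 3625 higher and 3969 lower, and 1842 and 2353 of these changed at least 2-fold. Camera called 17 of 25 lists, and Wnt target (adjusted p = 0.036), fetal-like and YAP target (0.036), squamous epithelium (0.036) and enteric neuron and glia genes (0.045) held with an estimated correlation. The other 13 did not (adjusted p = 0.084 to 0.61 with an estimated correlation). Camera calls of endothelial (adjusted p = 0.0965) and macrophage genes (0.131) were lost without shRenilla on dox 1, and that of ribosome biogenesis and Myc target genes (0.0578) without shRenilla on dox 2. Polyp and mucosa also differ in genotype of the hairpin and in tissue sampled, which this comparison cannot separate. Both on-dox mucosa libraries came from females and the polyps from both sexes.

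**Figure D2:**
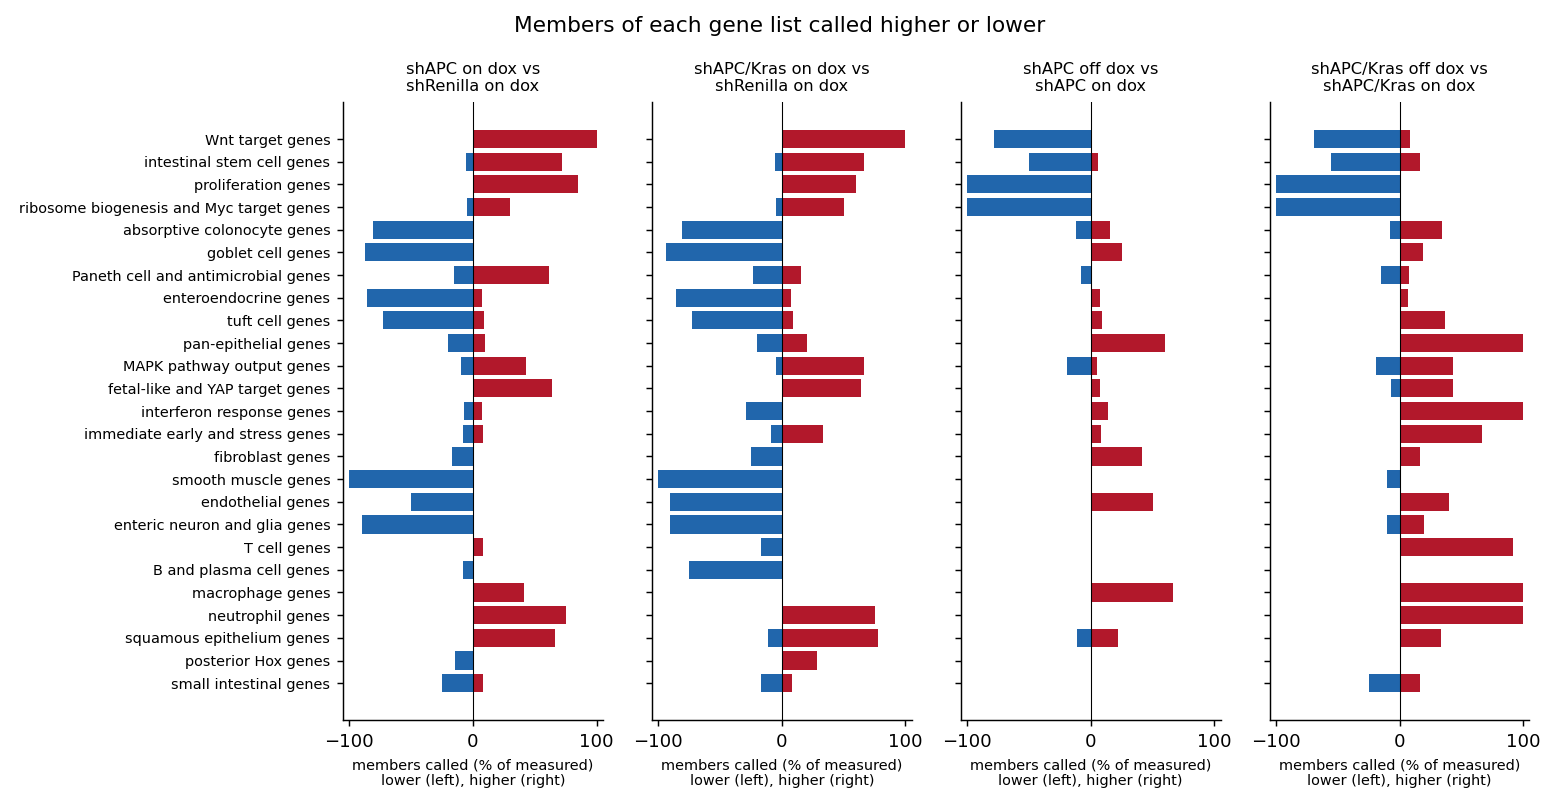
Percent of the measured members of each of 25 gene lists (vertical axis) called higher (red, right) or lower (blue, left) by edgeR in 4 comparisons (panels). Wnt target genes reach 23 of 23 higher in both polyp groups against mucosa, and proliferation genes reach 20 of 20 lower after dox withdrawal in both genotypes.

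Polyps that carry the Kras change as well were compared with the same on-dox mucosa. In shAPC/Kras polyps all 23 Wnt target genes were again higher, with Notum at 191 ± 20.7 CPM (log2 fold change 8.95 ± 0.53, adjusted p = 2.2e-08), Axin2 at 328 ± 53.9 CPM (3.13 ± 0.30), the homeobox factor Prox1 at 4.91 ± 0.38 and Myc, a growth-promoting transcription factor, at 2.15 ± 0.27. Intestinal stem cell genes were higher in 12 of 18 and lower in 1 (2 adjusted over the list alone). Proliferation genes were higher in 12 of 20 (13 adjusted over the list alone), but the 4 with the smallest p, such as the mitotic factor Foxm1 at 1.99 ± 0.50, were not called without shRenilla on dox 2, which for Foxm1 gave an adjusted p of 0.064. MAPK pathway output genes were higher in 14 of 21 and lower in 1, with Dusp4 at 2.61 ± 0.23 and the stress response gene Ier3 at 3.89 ± 0.49. Of 14 fetal-like and YAP target genes 9 were higher, among them the surface protein Msln, absent from most adult epithelium, at 5.91 ± 0.77. Ribosome biogenesis and Myc target genes were higher in 10 of 20 (14 adjusted over the list alone) and 1 was lower.

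Goblet cell genes were lower in 15 of 16 in shAPC/Kras polyps, with Muc2 at 440 ± 276 CPM against 6930 ± 5770 (log2 fold change -3.98 ± 0.55) and Fcgbp at -5.15 ± 0.65. The mean log2 CPM of the goblet list was 5.36 ± 0.65 in these polyps, 9.04 ± 0.48 in on-dox mucosa and 7.75 ± 0.71 in off-dox mucosa. Absorptive colonocyte genes were lower in 21 of 26, with Aqp8 at -7.08 ± 1.05 and the peptide hormone gene Guca2a at -4.59 ± 0.58. Smooth muscle genes were lower in 10 of 10, enteric neuron and glia genes in 9 of 10, endothelial genes in 9 of 10 and B and plasma cell genes in 9 of 12 (10 adjusted over the list alone). The leiomodin gene Lmod1, an actin nucleator of smooth muscle, was at -6.15 ± 0.45, the endothelial receptor Tek at -2.90 ± 0.34 and the plasma cell receptor Tnfrsf17 at -4.89 ± 0.59. Phox2b, a factor of autonomic neurons, had 0 counts over these polyps and was at least 185-fold lower than in mucosa. Desmosomal Dsg3, a cadherin of squamous epithelium, was 1900-fold higher than the 1 count over mucosa (counting interval 341 to 75200). Neutrophil genes were higher in 9 of 12, with Mmp9 at 3.99 ± 0.42. Interferon response genes were lower in 4 of 14 (3 adjusted over the list alone). The mean log2 CPM of that list was 3.149 in shRenilla on dox 1, within the range of these polyps (2.11 to 3.879), and 4.817 in shRenilla on dox 2.

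In all, edgeR called 8756 genes between shAPC/Kras polyps and mucosa on dox, 4148 higher and 4608 lower. Camera called 17 lists, of which Wnt target (adjusted p = 0.034), fetal-like and YAP target (0.034), squamous epithelium (0.034) and enteric neuron and glia genes (0.041) held with an estimated correlation, and the other 13 had adjusted p = 0.17 to 0.55 with an estimated correlation. The camera call of proliferation genes was lost without shRenilla on dox 2 (adjusted p = 0.108).

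The response of shAPC polyps to 4 days without dox, when Apc rises again, was read from off-dox against on-dox polyps. Proliferation genes fell in 20 of 20, with the replication helicase subunits Mcm5 (log2 fold change -1.94 ± 0.23, adjusted p = 3.7e-05), Mcm3 (-1.74 ± 0.20) and Mcm2 (-1.58 ± 0.15), and Mki67 went from 236 ± 72.4 to 77.8 ± 30.1 CPM (-1.60 ± 0.40). Ribosome biogenesis and Myc target genes also fell in 20 of 20, among them Cdk4 (-1.23 ± 0.11) and the nucleolar protein Ncl (-0.95 ± 0.08), and Myc fell by 1.33 ± 0.20 on the log2 scale. Wnt target genes fell in 18 of 23 and rose in none, with Axin2 going from 315 ± 52.1 to 116 ± 40.8 CPM (-1.44 ± 0.21) and cyclin D1, Ccnd1, at -1.48 ± 0.19. Intestinal stem cell genes fell in 9 of 18 (10 adjusted over the list alone) and rose in 1. Ascl2, a Wnt-driven stem cell factor, went from 25.7 ± 4.56 to 3.91 ± 1.77 CPM (-2.71 ± 0.37), and Lgr5 from 53 ± 23.9 to 16.7 ± 6.8 CPM (-1.67 ± 0.45).

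Rises in shAPC polyps after withdrawal were smaller in number among the lists of differentiated cells. Krt20 rose from 541 ± 233 to 1300 ± 246 CPM (log2 fold change 1.26 ± 0.32, adjusted p = 0.0072) and the adhesion molecule Ceacam20 by 1.31 ± 0.35, in a list of absorptive colonocyte genes of which 4 of 26 rose and 3 fell. The ketogenic enzyme gene Hmgcs2 was among those that fell (-1.77 ± 0.45). Goblet cell genes rose in 4 of 16, with Klf4 at 1.06 ± 0.24, and Muc2 did not pass (0.61 ± 0.46, adjusted p = 0.34). The mean log2 CPM of the goblet list was 6.785 and 6.5 in off-dox libraries 1 and 2, within the on-dox range (6.075 to 7.106). It was 7.596 and 8.285 in off-dox libraries 3 and 4. Pan-epithelial genes rose in 6 of 10 (7 adjusted over the list alone), with the adhesion protein Epcam going from 1750 ± 184 to 2420 ± 131 CPM. Macrophage genes rose in 8 of 12 (9 adjusted over the list alone), with the pore-forming Mpeg1 at 1.06 ± 0.26 and the surface receptor Emr1 at 1.00 ± 0.26. Among interferon response genes Mx1 (1.86 ± 0.61, adjusted p = 0.032) and Ifit3 (1.75 ± 0.60, 0.037) rose, while Oas1a (0.79 ± 0.30, 0.06) and Irf7 (1.00 ± 0.41, 0.081) did not pass. The mean log2 CPM of that list was 4.08 ± 1.20 on dox and 5.53 ± 0.43 off dox. Fibroblast genes rose in 5 of 12 (7 adjusted over the list alone), with the collagenase Mmp2 at 0.84 ± 0.21, and endothelial genes in 5 of 10 (6 adjusted over the list alone), with Emcn, a sialomucin of vessels, at 0.93 ± 0.22. Of 21 MAPK pathway output genes 1 rose and 4 fell. Those that fell were the ETS factors Etv4 (-1.12 ± 0.24) and Etv5 (-1.02 ± 0.32), and Myc and Ccnd1, which are also Wnt target genes. Among single genes, the lipoxygenase Alox15 fell by 3.32 ± 0.74 on the log2 scale, the receptor Lgr6 by 3.01 ± 0.83 and the matrix glycoprotein Thbs2 by 2.45 ± 0.51, while the phosphate transporter Slc34a2 rose by 2.12 ± 0.48 and the inflammasome protein Nlrp10 by 2.07 ± 0.29. Smooth muscle, neutrophil, T cell, B and plasma cell, and enteric neuron and glia lists had 0 members called by edgeR.

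For this withdrawal edgeR called 4869 genes, 2190 higher and 2679 lower, with 563 and 642 at least 2-fold changed, and 6811 had an unadjusted p under 0.05. The limma-voom test called 7860, of which 4786 were among the 4869. Sex was unequal between these groups: on-dox libraries 1, 3 and 4 came from females and 2 from a male, while off-dox library 3 came from a female and 1, 2 and 4 from males. With sex as a covariate, a setting added after the data were seen, edgeR called 4158 genes, of which 3896 were among the 4869. Camera called 10 lists, and the smallest p was that of ribosome biogenesis and Myc target genes (adjusted p = 8.6e-18, and adjusted p = 0.17 with an estimated correlation). None of the 10 held (adjusted p = 0.17 to 0.81 with an estimated correlation).

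The same question was asked of shAPC/Kras polyps after 4 days off dox, in which Kras itself rose from 187 ± 22.4 to 271 ± 25 CPM (log2 fold change 0.53 ± 0.12, adjusted p = 0.002). Proliferation genes again fell in 20 of 20 and ribosome biogenesis and Myc target genes in 20 of 20, with Mcm2 at a log2 fold change of -1.67 ± 0.16 (adjusted p = 1.3e-06), Ncl at -0.94 ± 0.08, the nucleolar methyltransferase Fbl at -1.24 ± 0.11 and Mki67 going from 183 ± 85.5 to 59.7 ± 15.7 CPM (-1.62 ± 0.40). Wnt target genes fell in 16 of 23 and rose in 2, with Axin2 going from 328 ± 53.9 to 96.5 ± 17.7 CPM (-1.76 ± 0.22) and Myc from 187 ± 53.8 to 58.5 ± 15.3 CPM (-1.68 ± 0.21). Intestinal stem cell genes fell in 10 of 18 and rose in 3; Lgr5 went from 41.3 ± 23.9 to 4.43 ± 2.28 CPM (-3.20 ± 0.49), Ascl2 fell by 2.86 ± 0.38 and the matricellular stem cell gene Smoc2 by 2.57 ± 0.35 on the log2 scale. Thbs2 (-3.54 ± 0.54) and the phospholipase Pla2g2a (-2.67 ± 0.42) fell as in shAPC polyps, where Pla2g2a was at -2.25 ± 0.41.

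Pan-epithelial genes rose in 10 of 10 in shAPC/Kras polyps, with Epcam going from 1640 ± 137 to 3100 ± 256 CPM (log2 fold change 0.92 ± 0.11). Absorptive colonocyte genes rose in 9 of 26 and fell in 2; Krt20 went from 564 ± 200 to 3020 ± 791 CPM (2.42 ± 0.33) and the sodium channel subunit Scnn1a rose by 1.71 ± 0.29, while Hmgcs2 fell by 3.69 ± 0.50. Goblet cell genes rose in 3 of 16, with Klf4 at 1.57 ± 0.25, and Muc2 did not pass (0.41 ± 0.46, adjusted p = 0.48). Immediate early and stress genes rose in 8 of 12, with the stress factor Atf3 going from 35.3 ± 2.01 to 263 ± 40.2 CPM (2.89 ± 0.23) and the mRNA decay factor Zfp36 at 2.04 ± 0.25. The list of MAPK pathway output genes rose in 9 of 21 and fell in 4, with Dusp4 at 1.13 ± 0.16 and Etv4 at -2.24 ± 0.24. Myc and Ccnd1, which are also Wnt target genes, were among those that fell. Fetal-like and YAP target genes rose in 6 of 14 and fell in 1, with Anxa1, an annexin of injured epithelium, at 1.05 ± 0.16.

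Genes of 4 immune lists rose in these shAPC/Kras polyps as well, and off-dox libraries 3 and 4, both from females, stood apart from 1 and 2, both from males. Interferon response genes rose in 14 of 14, macrophage genes in 12 of 12, neutrophil genes in 12 of 12 and T cell genes in 11 of 12, while the 12 B and plasma cell genes did not pass by edgeR (camera adjusted p = 0.46). The guanylate-binding protein Gbp2 went from 17.7 ± 15 to 944 ± 334 CPM (log2 fold change 5.73 ± 0.90), the interferon regulator Irf7 from 44.9 ± 20 to 319 ± 58.8 CPM (2.83 ± 0.44) and the mannose receptor Mrc1 rose by 2.43 ± 0.35. The neutrophil calprotectin gene S100a9 was at 30.5 ± 34.1 CPM on dox and 2860 ± 3220 CPM off dox (6.55 ± 1.33). Without off-dox libraries 3 and 4, a setting chosen after the data were seen, 20 of 26 called macrophage and interferon response members stayed called and 1 of 23 neutrophil and T cell members did, with an adjusted p of 0.12 for S100a9.

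Across genes, 8312 were called after withdrawal in shAPC/Kras polyps, 4384 higher and 3928 lower by edgeR, with 2090 and 1208 at least 2-fold changed. Without off-dox libraries 3 and 4 the number was 6497, of which 5774 were among the 8312. Camera called 10 lists and none held (adjusted p = 0.35 to 0.6 with an estimated correlation). For interferon response genes these were adjusted p = 1.6e-06 with the preset value and adjusted p = 0.4 with an estimated correlation. Neutrophil genes had adjusted p = 0.0014, adjusted p = 0.52 with an estimated correlation, and adjusted p = 0.0571 without off-dox libraries 3 and 4.

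**Figure D3:**
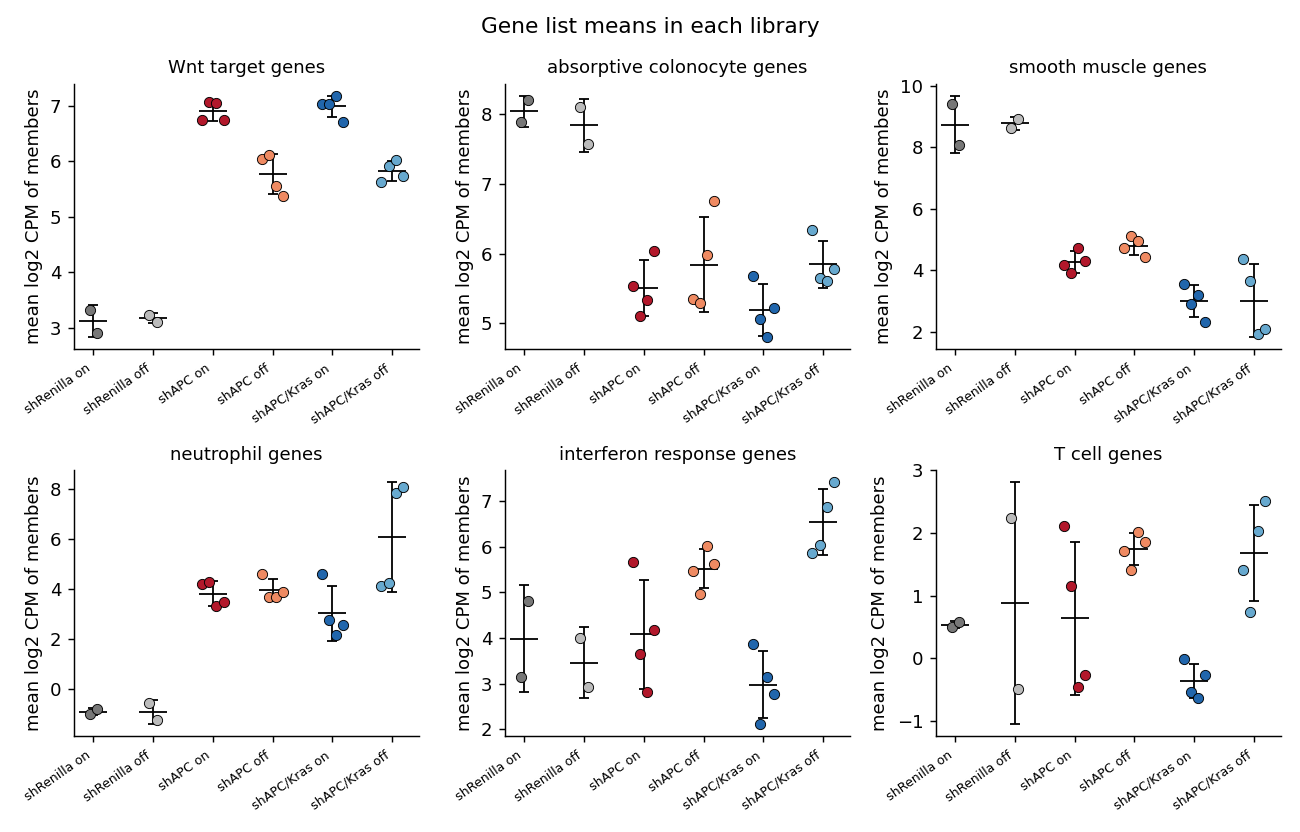
Mean log2 CPM of the members of 6 gene lists (vertical axes) in each library, by group; points are libraries, horizontal bars the group mean and whiskers 1 SD (n = 4 for polyps, n = 2 for mucosa). Neutrophil genes are highest in 2 of the 4 shAPC/Kras libraries off dox, and smooth muscle genes are lower in each of the 16 polyp libraries than in the 4 mucosa libraries.

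The withdrawal responses of the 2 genotypes share no libraries and were set beside each other. Of the genes that rose in shAPC polyps, 1710 also rose in shAPC/Kras polyps, where independent lists would share 552, and 2241 fell in both, against 605. Axin2, Lgr5, Ascl2, Ccnd1, Mcm2 and Ncl were among those that fell in both and Krt20, Klf4, Epcam and Apc among those that rose in both. Another 5 genes rose in shAPC and fell in shAPC/Kras polyps, and 5 fell in shAPC and rose in shAPC/Kras polyps. Log2 fold changes correlated across 14297 genes with Pearson's r of 0.62 and Spearman's rho of 0.75, with genes not being independent replicates. Of the 4869 genes called in shAPC polyps, 97.1% had the same sign in shAPC/Kras polyps, and their median log2 change along the shAPC direction was 0.65 in shAPC and 0.73 in shAPC/Kras polyps. Of the 8312 genes called in shAPC/Kras polyps, 93.5% had the same sign in shAPC polyps, with medians along the shAPC/Kras direction of 0.82 in shAPC/Kras and 0.46 in shAPC polyps.

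**Figure D4:**
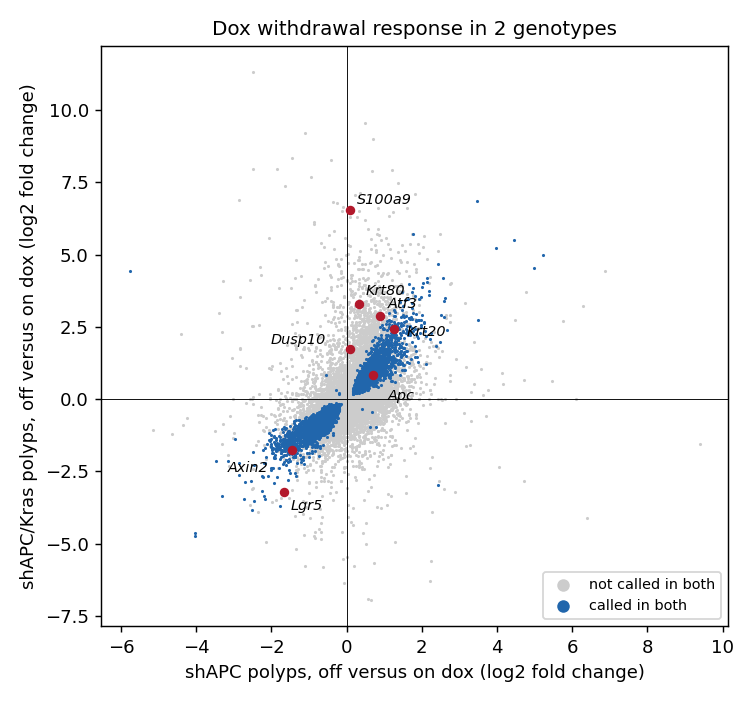
Log2 fold change after dox withdrawal in shAPC polyps (horizontal axis) and in shAPC/Kras polyps (vertical axis) for each tested gene; blue points were called in both, grey points were not, and red points are 8 named genes. Lgr5 (-1.67 and -3.20) and Axin2 (-1.44 and -1.76) lie low in both, and S100a9 rose only in shAPC/Kras polyps, a difference that did not pass its own test (adjusted p = 0.1).

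To see how many genes that set polyps apart moved back after withdrawal, calls against mucosa were crossed with withdrawal calls. In shAPC polyps 1363 genes higher than in mucosa on dox fell after withdrawal, such as Axin2, Lgr5 and Rnf43, and 976 lower genes rose, such as Klf4; independent lists would share 558 and 500. Another 206 of the higher genes rose further and 134 of the lower genes fell further, and 2056 and 2859 were not called after withdrawal. In shAPC/Kras polyps 1817 and 1438 moved back, against 936 and 1161, while 659 rose further, 345 fell further and 1672 and 2825 were not called. The on-dox polyps enter both sides. Simulated unchanged groups that shared them gave a mean r of -0.38 for shAPC and -0.40 for shAPC/Kras, beside observed values of -0.36 and -0.21. There was no overlap of calls in 10 draws. With no gene changed few calls are made, so this does not measure the overlap that sharing brings among changed genes. The observed covariance was -0.334 against a simulated -0.052 in shAPC and -0.357 against -0.056 in shAPC/Kras, differences of -0.282 and -0.301. With the on-dox polyps divided so that each side used a different pair of libraries, the total overlap was 1089 to 1574 genes in shAPC and 2107 to 2440 in shAPC/Kras over 6 splits, against 2339 and 3255 unsplit. Higher genes that fell numbered 769 to 1059 and 1180 to 1461. Lower genes that rose numbered 309 to 515 and 828 to 1075, beside 500 and 1161 for independent lists unsplit. Each side of a split holds fewer libraries, and the number that independent lists would share was not computed for the splits. Without shRenilla on dox 2 the totals were 1441 and 2022.

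What the Kras change adds while Apc is silenced was read from shAPC/Kras against shAPC polyps, both on dox. Etv4, a transcription factor switched on by MAPK signalling, was at 60 ± 3.53 CPM against 13 ± 4.49 (log2 fold change 2.21 ± 0.24, adjusted p = 0.00026), the MAPK inhibitors Spred1 and Spred2 were higher by 0.56 ± 0.10 and 0.53 ± 0.08, and Myc by 0.98 ± 0.20. MAPK pathway output genes were higher in 6 of 21 (9 adjusted over the list alone). Eda2r, a receptor of the tumour necrosis factor family, was at 28 ± 14.3 against 1.91 ± 0.469 CPM (3.87 ± 0.36), the cell cycle inhibitor locus Cdkn2a was higher by 3.06 ± 0.58, Msln by 2.52 ± 0.47 and Dsg3 by 1.81 ± 0.33. Paneth cell and antimicrobial genes were lower in 6 of 13 (9 adjusted over the list alone), with the lectin gene Reg4 at -2.86 ± 0.61. Goblet cell genes were lower in 4 of 16 (11 adjusted over the list alone) with Creb3l4, a factor of secretory cells, at -1.23 ± 0.27. Library 1 of shAPC/Kras on dox lay within the shAPC range of both lists in mean log2 CPM. For Paneth cell genes it was at 3.609 (others 0.842 to 1.64, shAPC 3.535 to 6.965), and for goblet cell genes at 6.331 (others 4.987 to 5.107, shAPC 6.075 to 7.106). B and plasma cell genes were lower in 5 of 12 (7 adjusted over the list alone), with the immunoglobulin joining chain Igj at 53.4 ± 59.7 against 705 ± 453 CPM (-3.72 ± 0.73). Endothelial genes were lower in 7 of 10 (9 adjusted over the list alone), fibroblast genes in 5 of 12 (11 adjusted over the list alone) and smooth muscle genes in 2 of 10 (8 adjusted over the list alone). Esam, an endothelial adhesion molecule, was at -1.15 ± 0.20 and the matrix protein Fbln1 at -1.79 ± 0.29. Library 1 of shAPC/Kras on dox again lay near the shAPC range in mean log2 CPM. For endothelial genes it was at 3.178 (others 1.735 to 2.349, shAPC 3.328 to 3.449). For fibroblast genes it was at 6.09 (others 4.748 to 5.494, shAPC 6.372 to 6.567). The comparison does not separate a change in the share of such cells from a change within cells. Apc (-0.07 ± 0.16), Kras (-0.01 ± 0.12), Axin2 (0.06 ± 0.21) and Krt20 (0.06 ± 0.31) did not pass, nor did any of the 20 proliferation genes.

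By edgeR 1227 genes were called, 503 higher and 724 lower, and 4201 had an unadjusted p under 0.05. The count moved with the libraries: 646 without shAPC on dox 1, 674 without shAPC on dox 2, 1902 without shAPC/Kras on dox 1, and 536, 668 and 546 without shAPC/Kras on dox 2, 3 and 4. DESeq2 called 2181, limma-voom 3416 and a fit of these groups alone 554. None of 15 lists that camera called held (adjusted p = 0.3 to 0.58 with an estimated correlation).

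After withdrawal the genotypes were compared again, shAPC/Kras against shAPC polyps off dox. MAPK pathway output genes were higher in 16 of 21 and lower in 1 (2 adjusted over the list alone), with the phosphatase Dusp6 at 444 ± 120 against 157 ± 65.4 CPM (log2 fold change 1.49 ± 0.26, adjusted p = 0.001), Dusp4 at 1.40 ± 0.16 and the ephrin receptor Epha2 at 1.58 ± 0.24. Cd44, a hyaluronan receptor, was higher by 1.61 ± 0.24, Msln by 3.49 ± 0.48, Anxa1 by 1.26 ± 0.16 and Atf3 by 1.78 ± 0.22. Immediate early and stress genes were higher in 8 of 12 (9 adjusted over the list alone) and pan-epithelial genes in 8 of 10 (10 adjusted over the list alone), with the tight junction protein Cldn4 at 1.17 ± 0.22. Fibroblast genes were lower in 11 of 12, endothelial genes in 10 of 10 and smooth muscle genes in 7 of 10, with collagen Col1a1 at 65.1 ± 9.98 against 310 ± 107 CPM (-2.25 ± 0.37), Col1a2 at -2.02 ± 0.29 and Esam at -1.43 ± 0.20. Goblet cell genes were lower in 9 of 16 (11 adjusted over the list alone) and higher in 2, with the trefoil peptide Tff3 at -1.77 ± 0.38. Paneth lysozyme, Lyz1, was at 2.41 ± 0.713 against 262 ± 200 CPM (-6.75 ± 1.39) and Krt20 was higher by 1.22 ± 0.32. Apc (0.07 ± 0.16), Axin2 (-0.26 ± 0.21) and Mki67 (-0.38 ± 0.39) did not pass.

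Of 4466 genes called by edgeR, 2449 were higher and 2017 lower. With shAPC/Kras libraries 3 and 4 left out 2128 were called, of which 1740 were among the 4466. The goblet cell call was lost without shAPC off dox 4 (adjusted p = 0.0613). Camera called 13 lists and none held (adjusted p = 0.28 to 0.67 with an estimated correlation).

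Whether the withdrawal response itself differed between genotypes was tested as an interaction. It was called for 10 genes by edgeR, of 3054 with an unadjusted p under 0.05. The 9 genes with a positive difference rose in shAPC/Kras polyps; in shAPC polyps Atf3 and Rhob rose, Gm9000 fell and the other 6 did not pass. Rhob, a stress-induced small GTPase, rose from 277 ± 30.6 to 889 ± 106 CPM in shAPC/Kras polyps and went from 330 ± 19.3 to 469 ± 47.7 CPM in shAPC polyps, a difference of 1.17 ± 0.16 on the log2 scale (adjusted p = 0.0088). Dusp10, a phosphatase of stress kinases, differed by 1.64 ± 0.23, Gnaq, a G protein subunit, by 0.78 ± 0.10, the ubiquitin ligase adaptor Kctd11 by 0.94 ± 0.15, Atf3 by 1.99 ± 0.30 and the keratin Krt80 by 2.98 ± 0.52. The neutrophil granule genes Mpo (6.92 ± 1.02) and Prtn3 (4.08 ± 0.63) were at 7.69 ± 0.692 and 2.51 ± 0.387 CPM in shAPC/Kras polyps off dox and below 1 CPM on average in every other group. Thrb, a thyroid hormone receptor, fell in shAPC/Kras polyps (-1.13 ± 0.20) and did not pass in shAPC polyps (0.45 ± 0.19), a difference of -1.57 ± 0.27 (adjusted p = 0.048). The gene model Gm9000 rose by 4.42 ± 1.22 in shAPC/Kras and fell by 5.76 ± 1.30 in shAPC polyps, a difference of 10.18 ± 1.78 (0.048), but it was at 78.7 to 119 CPM in shAPC on dox 1, 3 and 4 and shAPC/Kras off dox 3 and 4 and at most 2.67 CPM in the other libraries. Mpo, Prtn3, Gnaq, Kctd11 and Gm9000 fall outside the rule for named genes and were chosen after their values were seen. Differences for Lgr5 (-1.53 ± 0.64, adjusted p = 0.23), Krt20 (1.16 ± 0.44, 0.2), Axin2 (-0.32 ± 0.30, 0.6), Apc (0.13 ± 0.22, 0.79) and Gbp2 (3.99 ± 1.08, 0.11) did not pass. Neutrophil genes had 0 members called over all genes and 11 of 12 adjusted over the list alone, and interferon response genes 0 and 10 of 14 adjusted over the list alone.

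DESeq2 called 858 genes for this difference and limma-voom 2358. The edgeR count was 5 without shAPC on dox 3, 6 without shAPC on dox 4, 35 without shAPC/Kras on dox 1, 19 without shAPC/Kras off dox 1, 408 without shAPC/Kras off dox 2, 4 without shAPC/Kras off dox 4, and 4, 6 and 3 without shAPC off dox 1, 2 and 3. Without shAPC/Kras off dox 3 and 4 together it was 2, and Rhob and Dusp10 (adjusted p = 0.061 each) and Atf3 (0.093) were not called. The call of Krt80 was lost without any of shAPC on dox 2, 3 and 4 (adjusted p = 0.068, 0.084 and 0.11), shAPC/Kras on dox 2, 3 and 4 (0.097, 0.12 and 0.065), shAPC/Kras off dox 1, 3 and 4 (0.053, 0.098 and 0.12) and shAPC off dox 1, 2, 3 and 4 (0.12, 0.12, 0.08 and 0.073). That of Thrb was lost without any of shAPC on dox 1, 3 and 4 (0.13, 0.084 and 0.11), shAPC/Kras on dox 2 and 3 (0.097 and 0.12), shAPC/Kras off dox 3 and 4 (0.11 each) and shAPC off dox 1, 2, 3 and 4 (0.12, 0.12, 0.055 and 0.07). Atf3 was not called without shAPC/Kras off dox 4 (adjusted p = 0.059), shAPC off dox 1 (0.051) or shAPC off dox 3 (0.051). Camera called 6 lists, neutrophil (adjusted p = 2.6e-05), interferon response (5.3e-06), pan-epithelial (0.0003), immediate early and stress (0.0015), ribosome biogenesis and Myc target (0.026) and macrophage genes (0.044). None held (adjusted p = 0.57 to 0.89 with an estimated correlation).

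Polyps off dox were also set against off-dox mucosa to see what remained different 4 days after withdrawal. In shAPC polyps 18 of 23 Wnt target genes were still higher, with Notum at 95.4 ± 41.3 against 0.476 ± 0.14 CPM (log2 fold change 7.63 ± 0.50, adjusted p = 8e-08) and Axin2 at 116 ± 40.8 against 35.5 ± 0.28 CPM (1.71 ± 0.28). Of 14 fetal-like and YAP target genes 7 were higher (8 adjusted over the list alone), with Tacstd2 at 7.83 ± 0.62. Absorptive colonocyte genes were lower in 16 of 26, with the carbonic anhydrase Car2 at -2.16 ± 0.31, and smooth muscle genes in 10 of 10, while Krt20 (0.53 ± 0.39) and Muc2 (-0.06 ± 0.56) did not pass. For Muc2 the mucosa level differed as well, with 6930 ± 5770 CPM on dox and 1890 ± 947 off dox, against 1190 ± 296 and 1820 ± 900 in shAPC polyps. Proliferation genes were lower in 5 of 20 (8 adjusted over the list alone), with the thymidylate synthase Tyms at -1.23 ± 0.24. The mean log2 CPM of this list was 3.93 ± 0.33 in these polyps, 4.73 ± 0.01 in off-dox mucosa and 3.90 ± 0.83 in on-dox mucosa. Of 5652 genes called, 2575 were higher and 3077 lower, with 3444 called without shRenilla off dox 1 and 3307 without shRenilla off dox 2. Camera called 16 lists; fetal-like and YAP target (adjusted p = 0.025) and squamous epithelium genes (0.0059) held with an estimated correlation and the other 14 did not (adjusted p = 0.057 to 0.59 with an estimated correlation). The log2 fold changes against mucosa on and off dox correlated with r of 0.80 across genes, with 1518 genes higher in both and 2053 lower in both, against 536 and 702 for independent lists.

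In shAPC/Kras polyps off dox 18 of 23 Wnt target genes were higher than in mucosa, with Notum at 7.06 ± 0.49 and Axin2 at 1.44 ± 0.28. MAPK pathway output genes were higher in 15 of 21 and lower in 1 (2 adjusted over the list alone), with Dusp4 at 4.14 ± 0.25 (adjusted p = 7.2e-09) and the growth factor Hbegf at 4.08 ± 0.47. Fetal-like and YAP target genes were higher in 11 of 14, with Tacstd2 at 173 ± 50 against 0.307 ± 0.289 CPM, and immediate early and stress genes in 10 of 12, with Fosb, a factor of the AP-1 family, at 4.33 ± 0.63. Proliferation genes were lower in 14 of 20 (17 adjusted over the list alone), with Mcm2 at -1.18 ± 0.18, while Krt20 was higher by 1.75 ± 0.42. The mean log2 CPM of the proliferation list was 3.61 ± 0.27 in these polyps, 4.73 ± 0.01 in off-dox mucosa and 3.90 ± 0.83 in on-dox mucosa. Absorptive colonocyte genes were lower in 15 of 26 and higher in 5 (6 adjusted over the list alone), with Guca2a at -4.40 ± 0.57. Of 9227 genes called, 4329 were higher and 4898 lower. Fetal-like and YAP target (adjusted p = 0.033) and squamous epithelium genes (0.018) held with an estimated correlation among 19 lists called by camera, and the other 17 did not (adjusted p = 0.12 to 0.57 with an estimated correlation). The correlation with the on-dox comparison was 0.74 across genes, with 1981 genes higher in both and 2866 lower in both, against 1032 and 1297 for independent lists.

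Mucosa off dox against mucosa on dox measured what dox withdrawal does without an Apc hairpin. By edgeR 48 genes were called, 13 higher and 35 lower, of 2957 with an unadjusted p under 0.05. Sprr1a, a cornified envelope protein, fell from 15.6 ± 7.57 to 1.31 ± 0.403 CPM (log2 fold change -3.56 ± 0.51, adjusted p = 0.019) and the selenium-binding protein gene Selenbp2 fell by 3.80 ± 0.61, while Lpar2, a receptor for lysophosphatidic acid, rose by 1.63 ± 0.29 and the centromere protein gene Cenpl by 1.16 ± 0.20. Apc (0.09 ± 0.22), Axin2 (-0.07 ± 0.30), Lgr5 (0.07 ± 0.65), Mki67 (1.58 ± 0.56), Krt20 (-0.63 ± 0.44) and Muc2 (-1.88 ± 0.66) did not pass, and squamous epithelium genes, through Sprr1a, were the 1 list with a member called. None of these calls held in every fit that left out 1 mucosa library. Sprr1a was lost without shRenilla on dox 1 (adjusted p = 0.057), off dox 1 (0.072) or off dox 2 (0.059), and Selenbp2 without off dox 1 (0.072) or off dox 2 (0.096). Lpar2 was lost without on dox 1 (0.095), on dox 2 (0.077) or off dox 1 (0.14), and Cenpl without on dox 1 (0.095), on dox 2 (0.067), off dox 1 (0.1) or off dox 2 (0.076). The count was 1 without shRenilla on dox 1, 120 without shRenilla on dox 2 and 2 without shRenilla off dox 1; DESeq2 called 841, limma-voom 15, a fit of these groups alone 2, and with sex as a covariate 12 were called. Both on-dox mucosa libraries came from females and both off-dox libraries from males, so dox and sex coincide here. The count leaves out genes that plainly differed: Xist, expressed from the inactive X, was at 814 and 564 CPM on dox and 0.831 and 0.823 CPM off dox, and Ddx3y, a helicase gene of the Y chromosome, at 0.0426 and 0 CPM and at 71.2 and 78.4 CPM, yet neither was called (adjusted p = 0.24 and 0.32) in the fit over all groups, where polyp groups hold both sexes. Camera called 6 lists and none held (adjusted p = 0.93 with an estimated correlation).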

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

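The second marker lists for muscle and nerve and the comparison with sex in polyps were set before their results were seen; the other explanation tests and the splits of the libraries were chosen after.

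Smooth muscle genes were lower in 10 of 10 and enteric neuron and glia genes in 9 of 10 in both on-dox polyp groups against mucosa. Actin Acta2 stood at 907 ± 461 CPM in on-dox mucosa, 83.3 ± 18.2 in shAPC and 32.8 ± 12.9 in shAPC/Kras polyps, and Des at 907 ± 608, 11.5 ± 6.88 and 5.63 ± 1.72 CPM. A loss of all non-epithelial cells alike was excluded, as the median log2 change of fibroblast genes lay 4.62 above that of smooth muscle genes in shAPC polyps, against an SD of 0.96 among fibroblast and 1.04 among smooth muscle members. A candidate explanation is less muscle wall in the polyp samples: in second lists of 21 muscle and interstitial cell genes and 20 neuron and glia genes, none of them in another list, at least 85% were called lower in both comparisons. A change within these cells that the hairpin or the tumour brings was not tested and stays open.

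Interferon response, macrophage, neutrophil and T cell genes rose after withdrawal in shAPC/Kras polyps, with S100a8 at 1780 ± 1960 and S100a9 at 2860 ± 3220 CPM off dox. A lower epithelial share that raised every other cell type alike was excluded, since 17.6% of fibroblast, endothelial and B cell members rose. Pan-epithelial genes rose in 10 of 10, but levels per cell can change, so they do not measure the share of cells. A lower share brought by a gain of only some cell types was not tested. A sex difference of the same size in all groups was excluded, since with sex as a covariate 98% of the 49 called members stayed called. Off-dox libraries 3 and 4 alone were excluded for macrophage and interferon genes, of which 76.9% of 26 called members stayed called without them. For T cell genes the mean log2 CPM in off-dox libraries 1 and 2 (1.41 and 0.743) lay at least 0.76 above the on-dox libraries (-0.631 to -0.013, SD 0.278). That gap is smaller than the SD of 1.22 among shAPC polyps on dox, so libraries 3 and 4 alone were not excluded for this list. Without them the median log2 change of the 11 called members went from 2.73 (SD 0.65, median SE 0.70) to 1.57 (SD 0.49, median SE 0.76). The calls of these members ended, with the smaller change and the fewer libraries not separated. For the neutrophil list these libraries alone stay open: libraries 1 and 2 (4.1 and 4.25) lay within the on-dox range (2.17 to 4.62, a gap of -0.51), and the 1 of 12 members that stayed called without 3 and 4 decides nothing, since the pair left out was the highest in these genes; the granule genes Mpo and Prtn3, outside that list and picked after their values were seen, go against it for themselves, with 6.89 and 7.36 and with 2.1 and 2.28 CPM in libraries 1 and 2 against at most 0.258 and 0.13 on dox. Libraries 3 and 4 came from females and 1 and 2 from males, so a sex difference within this group cannot be told apart from other differences between these libraries, and an effect of Apc or Kras on immune cells was not tested.

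Between mucosa off and on dox 48 genes were called, 1 without shRenilla on dox 1, 120 without shRenilla on dox 2 and 2 without shRenilla off dox 1. A sex difference shared by polyps and mucosa cannot be told apart from a response to dox: these genes moved by a median of 0.03 (SD 0.18) on the log2 scale between male and female polyps along the mucosa direction, 66.7% of them that way, against 0.90 in mucosa (a ratio of 0.036), but the fit called 0 of 5 sex-linked genes by edgeR, adjusted p = 0.24 for Xist, so genes that differ by sex in the polyp groups, which hold both sexes, were largely kept out of the 48. With sex as a covariate 12 genes were called, 9 of them among the 48. Without the library shRenilla on dox 1 the median change of the 48 genes kept 0.93 of its size (1.1 without shRenilla on dox 2). These genes were called with that library in the fit, which favours genes on which both on-dox libraries agree. The ratio therefore cannot exclude that library as the whole origin, which stays open. Why the number of calls fell without it was not tested. A sex difference confined to mucosa stays open too, since sex and dox coincide in these 4 libraries.

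Splits of the same libraries into other groups tested whether chance could give as many called genes. For shAPC polyps off against on dox, 1 of 35 splits, the real one, gave as many (4869, against 2 at most in the others). It was also 1 of 35 for shAPC/Kras polyps off against on dox (8312 against 1081), for shAPC/Kras against shAPC polyps on dox (1227 against 29) and for the same pair off dox (4466 against 1). In each of these 4 comparisons the real grouping gave the most calls, and 1 of 35 is the smallest share possible. The other splits mix libraries from both groups, which widens the spread within groups and holds their counts low. Chance is therefore bounded only by that share, and the gap in counts adds nothing to it. For the difference of the withdrawal responses 5 of 100 splits gave as many as the real 10, and the highest gave 3839, so chance was not excluded. That split left the shAPC/Kras libraries in their dox groups and mixed those of shAPC, so the structure of the samples it points to includes the dox response itself, and such splits are a poor measure of chance for this difference.

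The difference of withdrawal responses passed its test for Mpo (6.92 on the log2 scale), Prtn3 (4.08), Gm9000 (10.18), Krt80 (2.98), Atf3 (1.99), Dusp10 (1.64), Rhob (1.17), Kctd11 (0.94), Gnaq (0.78) and Thrb (-1.57). Without single libraries this count of 10 was 5 (shAPC on dox 3), 6 (shAPC on dox 4), 35 (shAPC/Kras on dox 1), 19, 408 and 4 (shAPC/Kras off dox 1, 2 and 4), and 4, 6 and 3 (shAPC off dox 1, 2 and 3). With the preset correlation it also passed for interferon response (median 2.26), neutrophil (3.17), immediate early and stress (0.98), macrophage (0.52), pan-epithelial (0.47) and ribosome biogenesis and Myc target genes (-0.19), with adjusted p = 0.57 to 0.89 with an estimated correlation.

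In groups of 4, a library's value far from the others was found in 28 of 312 tests (8.97%). Chance flags about 1 in 20 groups. In shAPC polyps on dox, library 3 had 39% of reads naming no gene (others 38 to 38.1), 4.24% of counts in the 10 most abundant genes (5.01 to 5.16) and 32.5 CPM of Ascl2 (22.8 to 24.4). Library 1 of that group had a mean log2 CPM of posterior Hox genes of -0.0403 (4.46 to 5.07) and 42.3 CPM of Cxcl9 (1.28 to 1.99), library 2 a mean of proliferation genes of 5.09 (5.7 to 5.71) and library 4 54.3 CPM of Atf3 (35.3 to 37.4). In shAPC polyps off dox, library 3 had 2.15% of mitochondrial counts (2.28 to 2.29) and library 1 127 CPM of S100a9 (37.9 to 50.8). Library 4 of the same group had 254 CPM of Kras (210 to 215), 176 of Car4 (2.84 to 32.3), 157 of Slc26a3 (5.94 to 28.6) and 65.8 of Aqp8 (3.34 to 10.7).

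Among shAPC/Kras polyps on dox, library 1 had a mean log2 CPM of goblet cell genes of 6.33 (others 4.99 to 5.11) and of B and plasma cell genes of -0.432 (-1.86 to -1.7). In CPM it had 61.7 of Apc (42.6 to 45.4), 55.9 of Car4 (1.32 to 2.5), 52 of Slc26a3 (3.77 to 7.18), 142 of Igj (12.2 to 30.3) and 124 of Lyz1 (2.3 to 4.09). It also had 65.9 of Reg4 (31.8 to 37.6), 54.8 of S100a8 (3.93 to 9.71), 81.1 of S100a9 (7.43 to 17.9), 88.3 of Reg3b (0.763 to 9.62) and 257 of Thbs2 (132 to 137). Library 2 of that group had a mean of small intestinal genes of 4.47 (-0.748 to 0.0198). In shAPC/Kras polyps off dox, library 1 had 36.2 CPM of Slc26a3 (12.6 to 15.6) and library 2 17.7 CPM of Etv4 (10.5 to 11.2).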

How the results depend on the processing

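Sex as a covariate and the fits without shAPC/Kras off dox 3 and 4 were chosen after the data were seen; the other alternatives were planned. Outside fits that left out single libraries, 8157 gene results kept their direction and side of the threshold, 331 were no longer called, 289 became called and 1 reversed, while 1194 list results stayed, 130 were lost and 26 gained. Scalings differed by at most 0.044 on the log2 scale. With limma-voom, calls rose to 7860 (shAPC off against on dox), 3416 (shAPC/Kras against shAPC on dox) and 2358 (difference of responses) and were 15 in mucosa off against on dox; with DESeq2 they were 2181, 858 and 841 for the last 3 of these. With only the groups compared, 554 (shAPC/Kras against shAPC on dox) and 2 (mucosa) were called, with no filter 25 and with sex as a covariate 12 in mucosa. Without shAPC/Kras off dox 3 and 4, shAPC/Kras against shAPC off dox had 2128 calls, the difference of responses 2, and Reg3b after withdrawal in shAPC/Kras turned to -2.51. Camera lists called fell from 129 to 12 with an estimated correlation. The fits of the groups compared alone and those without libraries 3 and 4 hold fewer samples; for the others the cause was not tested.

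The replicate numbers do not pair the samples: same-number correlations were -0.2 to 0.2, and no more than 1 of 4 samples correlated best with its own number in any pair of polyp groups. Among pairs of groups with mucosa, which share 2 numbers, it was 2 of 2 for mucosa on and off dox (correlation 0.14) and for shAPC polyps and mucosa off dox, and 0 or 1 of 2 in the others. With the number as a block, the difference of responses had 4 calls and mucosa off against on dox 87.

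Leaving out each library gave 536 to 1902 calls for shAPC/Kras against shAPC polyps on dox, 3 to 408 for the difference of responses, 3307 to 5232 for shAPC polyps against mucosa off dox and 1 to 120 for mucosa off against on dox. Genes that polyps and mucosa differ in and that moved back numbered 1441 to 2328 in shAPC and 2022 to 3559 in shAPC/Kras, both lowest without shRenilla on dox 2. Lct after withdrawal in shAPC/Kras ranged from -4.99 to 0.05 (without on dox 2). Against mucosa off dox in shAPC, Ms4a1 ranged from -5.96 to 0.69, Cr2 from -6.71 to 1.44 and Cd19 from -6.40 to 0.91, each highest without shRenilla off dox 1. A lone library left in a mucosa group was assumed to vary like the others.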

Other observations

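Secretory and other minor cell types that the comparisons above leave out also differed between polyps and mucosa on dox. Enteroendocrine genes were lower in 12 of 14 (13 adjusted over the list alone) in shAPC polyps and in 12 of 14 in shAPC/Kras polyps, with 1 higher in each. Chromogranin Chga, a granule protein of hormone cells, was at log2 fold changes of -2.90 ± 0.44 and -3.54 ± 0.45, and camera gave adjusted p = 8.4e-05 and 0.0001, with adjusted p = 0.24 and 0.2 with an estimated correlation. Tuft cell genes were lower in 8 of 11 in both (9 adjusted over the list alone in shAPC/Kras). Paneth cell and antimicrobial genes were higher in 8 of 13 (10 adjusted over the list alone) and lower in 2 in shAPC polyps, and higher in 2 and lower in 3 in shAPC/Kras polyps. Squamous epithelium genes were higher in 6 of 9 in shAPC polyps, with 1 lower when adjusted over the list alone, and in 7 of 9 in shAPC/Kras polyps (8 adjusted over the list alone), with 1 lower. After withdrawal they rose in 2 and fell in 1 in shAPC and rose in 3 in shAPC/Kras polyps, where Sprr1a rose by 2.60 ± 0.32. Posterior Hox genes were lower in 1 of 7 in shAPC and higher in 2 (5 adjusted over the list alone) in shAPC/Kras polyps. In shAPC polyps the median log2 fold change of the list was nonetheless 2.59 and its mean 1.67. The mean log2 CPM of the list was -0.04 in shAPC on dox 1 and 4.455 to 5.073 in the other libraries of that group. It was 4.963 to 6.134 in shAPC/Kras polyps on dox and 2.74 and 3.041 in on-dox mucosa. Small intestinal genes were higher in 1 of 12 in both polyp groups, with 3 (2 adjusted over the list alone) and 2 lower.

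Some genes stood apart in single libraries, all picked after their values were seen. Hoxd13, a factor of the hindmost gut, was at 0.131 CPM in shAPC on dox 1, 0.391 in shAPC off dox 3, 8.82 to 12.8 in 3 mucosa libraries, 254 in shRenilla off dox 2 and 151 to 406 in the other polyps. The sucrase gene Sis was at 126 CPM, Apoa4 at 132, Apoa1 at 92.3 and lactase, Lct, at 19.7 CPM in shAPC/Kras on dox 2. Gm9000 was at 78.7 to 119 CPM in shAPC on dox 1, 3 and 4 and shAPC/Kras off dox 3 and 4 and at most 2.67 in the others. Xist, expressed from the inactive X, was at 26.7 CPM in shAPC/Kras off dox 1 and 25.9 in shAPC off dox 4, libraries with genes of the Y chromosome.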
